A study of Vitis hybrid cultivar with 60 samples.

How the data were processed

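Bud RNA of 60 samples from 2 grape cultivars, Marquette and Brianna, was stated to have been sequenced after field chilling or controlled chilling at 4 °C. Libraries were single-end and made from poly-A selected RNA with a TruSeq kit, per the labels' protocols. FastQC, MultiQC, Trimmomatic, STAR and featureCounts are named in the submitters' processing notes, with no version, order or setting. The genome build and the annotation are not given in the sources used here. One table of the whole series was deposited by the authors, with counts per row that had not been normalized, judging from whole numbers whose totals differ between libraries. The unit was called counts for the form of the values alone. Their distribution, described in the results, lies close to that of equal-chance sampling noise, and they were not taken to measure transcripts.

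Each of the 60 columns bears the library name that the labels give for 1 sample, so all columns were matched and 0 were left out. No row lacked an identifier and none was a total. Groups were taken from the sample titles. No genome, annotation or table of gene names was used, so rows were not matched to genes. The 34 gene lists, which were patterns on product names, were not tested for this reason, and no gene was named. The rule for named genes, fixed before the data were examined, was to name those with the largest changes among rows past the threshold, and 0 rows passed.

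All 60 libraries entered 1 edgeR quasi-likelihood fit with a mean for each of the 20 groups, TMM normalization and the filterByExpr filter, which kept all 20000 rows. TMM factors lay between 0.9996 and 1.0004. A row was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the rows of each comparison and not across comparisons or alternatives. The 25 comparisons and the alternatives were fixed before the data were examined. The comparisons were controlled against field chilling per cultivar, its difference between cultivars, the change from 20 November to 4 March per arm and its difference between treatments, any change over the 5 points, Brianna against Marquette per treatment, and controlled against field at each point. The alternatives were DESeq2-type size factors (RLE), DESeq2, limma voom with sample weights, no filter, a filter of at least 5 CPM in at least 3 libraries, a fit on only the libraries compared, the replicate number as a block, and leaving out each library in turn. The blocks were numbered within each cultivar, so with them Brianna against Marquette did not compare the cultivar means.

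Whether the replicate numbers 1 to 3 pair the samples was checked within each cultivar from deviations of log2 CPM (prior count 2) from the group means. The fits were tested on simulated data with the real library sizes, in which 200 of 20000 rows were changed, 50 at each size of rise. These data held counting noise alone (Poisson), with no added spread between replicates. To describe the table, 200 tables were simulated in which the total of each library was dealt to the rows with an equal chance, and 13 statistics were compared with them. Library totals were compared by 2-sided permutation tests with 100000 resamples. Library totals of 10.5 to 49.9 M counts (M, 1000000) give each row at least 437 counts per library. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.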

Results

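In the deposited table all rows had nearly the same count within a library, 0 rows passed the edgeR test in any of 25 comparisons of treatments, cultivars and dates, and nothing about grapevine biology can be read from it. Buds of the hybrid grape cultivars Marquette and Brianna were the stated material, and RNA sequencing of poly-A selected RNA was the stated assay. The table gives whole-number counts for 20000 rows in 60 libraries. Row identifiers have the form of human Ensembl gene identifiers and carry the numbers 1 to 20000 without a gap, although the organism is a grape hybrid. No row was tied to a grapevine gene here, so no gene, pathway or genomic position is named below, and the 34 gene lists fixed before the data were examined were not tested.

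The 60 libraries fell into 20 groups of 3, made of 2 cultivars, 2 chilling treatments and 5 sampling points. Field buds were chilled on the vine. Controlled buds were cut as single nodes on 7 November 2018 and kept at 4 °C in the dark. The sampling points were 20 November 2018, 27 or 28 December 2018, 12 or 13 January 2019, 12 February 2019 and 4 March 2019. The December points of the field and controlled arms were 1 day apart, as were the January points of Marquette and Brianna. The design text speaks of 4 chilling periods, whereas the sample titles give 5 dates, and all 5 were used. The letters M and B in the titles were read as Marquette and Brianna, the cultivars that the design text names.

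Total counts per library ranged from 10.5 to 49.9 M (M, 1000000 counts), with a median of 35.8 M. The mean total was 35.7 ± 14.6 M in field Marquette and 34.8 ± 11.6 M in controlled Marquette (SD, n = 15 each). It was 27.4 ± 10.6 M in field Brianna and 34.3 ± 11.3 M in controlled Brianna (SD, n = 15 each). A permutation test of these totals, 2-sided, gave an adjusted p of 0.91 for controlled against field in Marquette and 0.19 in Brianna, over a family of 4 comparisons. The same family gave adjusted permutation p values of 0.19 for Brianna against Marquette in the field and 0.91 under controlled chilling. Differences in total counts between these arms could not be told from the spread between libraries. Whether the totals reflect sequencing depth was not tested.

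Within each library every row had nearly the same count. No row was at 0 in any library, the lowest of all values was 437 and the highest was 2725. The highest row exceeded the lowest row of the same library by a factor of 1.17 to 1.42. Averaged over the 60 libraries, row means ran from 1634 to 1674, with a coefficient of variation of 0.316%. The 10 highest rows of a library took between 0.0535% and 0.0578% of its counts, against 0.05% for 10 rows of equal size. The variance of counts over rows, divided by their mean, lay between 0.984 and 1.03 in the 60 libraries. Counting noise alone, with an equal share of reads for every row, gives a ratio of 1.

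**Figure D1:**
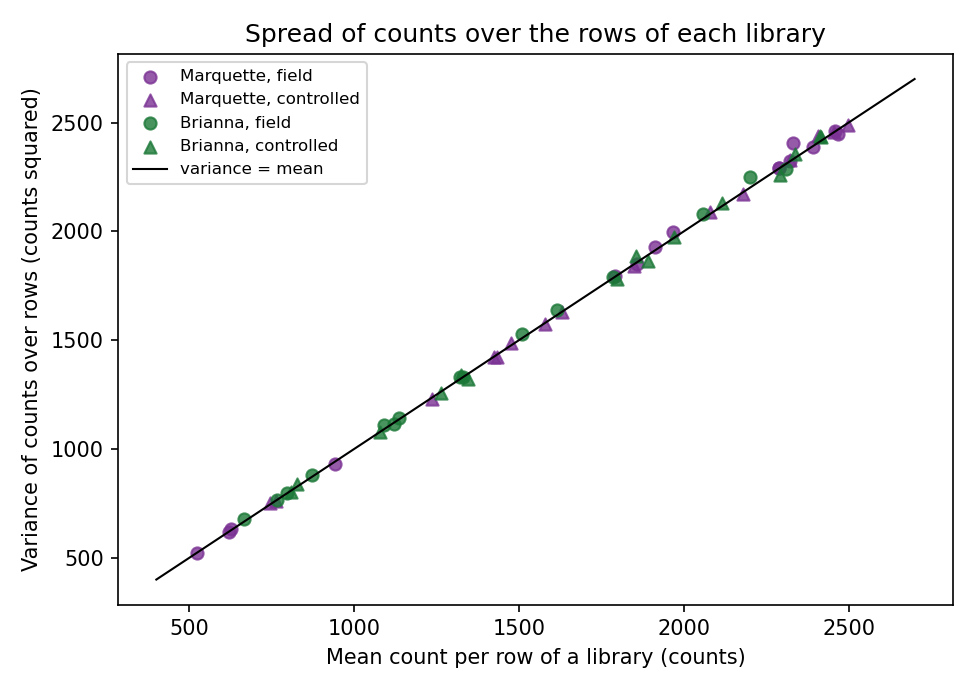
Variance of the counts over the 20000 rows of a library (vertical axis, counts squared) against their mean (horizontal axis, counts), 1 point per library, with colour for the cultivar and shape for the chilling treatment. All 60 libraries lie along the line on which variance equals mean, with ratios from 0.984 to 1.03.

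Replicates resembled each other no more than libraries of different groups did. Chi-square tests of counts over rows gave p under 0.05 for 6 of the 60 replicate pairs and for 128 of the 1710 pairs from different groups. Chance gives 3 and 85.5, and the pairs are not independent because each library enters many of them. The mean chi-square per degree of freedom was 1.003 in both kinds of pair. Adjusted over the 60 replicate pairs alone, 1 passed, and adjusted over all 1770 pairs, 0 passed. Nearly all pairs agreed within sampling noise, whatever their group. A copied library would give a chi-square of 0, but the lowest value per degree of freedom was 0.972, and 0 pairs of libraries were identical. No library was thus an exact copy of another, and each was kept as 1 sample. Nothing in the labels says whether replicates came from separate vines, so p-values measure only the spread between these libraries.

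Controlled against field chilling, the comparison of buds held in a cooler with buds on the vine, gave 0 rows past an adjusted p of 0.05 in either cultivar (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The contrast averaged the 5 sampling points, with 15 libraries in each arm. In Marquette 942 of 20000 rows had an unadjusted p under 0.05, and in Brianna 978 did, where chance alone gives 1000. No row differed by more than 3.34% in Marquette or 4.27% in Brianna, and the median standard error of a log2 fold change was 0.013 and 0.014. The difference between the cultivars in this contrast also gave 0 rows, with 954 at an unadjusted p under 0.05. DESeq2 and limma voom also called 0 rows in each of these contrasts. DESeq2 was conservative on these counts, with 381, 451 and 437 rows at an unadjusted p under 0.05 in Marquette, in Brianna and in their difference, where chance gives 1000.

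**Figure D2:**
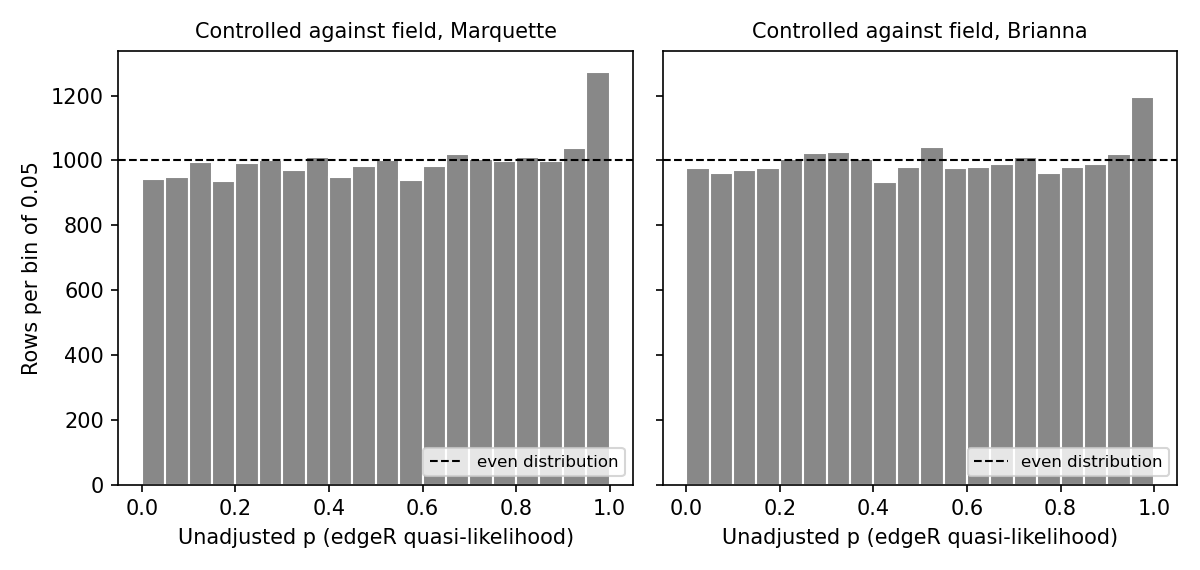
Number of rows (vertical axis) in each bin of 0.05 of the unadjusted edgeR p (horizontal axis), for controlled against field chilling in Marquette (left) and Brianna (right), with a dashed line at the 1000 rows per bin of an even distribution. Bins hold from 934 to 1274 rows, and neither cultivar has an excess of rows in the lowest bin. The bin from 0.95 upward holds the most rows in both, 1274 in Marquette and 1196 in Brianna, so the distribution is not even.

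Taken at single sampling points, 3 controlled libraries against 3 field libraries gave 0 rows in each of the 10 comparisons (edgeR, adjusted p). Leaving out controlled replicate 3 of Brianna gave 1 row in January (edgeR, adjusted p = 0.00871). The same omission on 12 February gave 1 row there (edgeR, adjusted p = 0.0487). The number of rows with an unadjusted p under 0.05 lay between 862, in Marquette on 4 March, and 1018, in Brianna on 12 February. The largest single difference, in Brianna on 12 February, was 11.1%, on 1 row.

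Change over the winter was compared between 4 March and 20 November within each cultivar and treatment. The 4 comparisons each gave 0 rows (edgeR, adjusted p), with 880 and 952 rows at an unadjusted p under 0.05 in field and controlled Marquette and 1009 and 963 in field and controlled Brianna. The smallest adjusted p of all comparisons, 0.057, belonged to 1 row in controlled Marquette, at position 7765 of the table. There limma voom called this row (adjusted p = 0.0488), as did edgeR on only the 6 libraries compared (adjusted p = 0.0475), and leaving out 1 library gave 0 to 2 rows, with 2 without replicate 2 of 20 November and 1 without replicate 3 of 4 March. The test for a change at any of the 5 sampling points gave 0 rows in the 4 arms as well, with 884 to 1015 rows at an unadjusted p under 0.05. In this test limma voom also called 0 rows, but put 1399 rows of field Marquette and 1387 of controlled Brianna at an unadjusted p under 0.05, against 884 and 914 with edgeR and 1000 by chance. The difference between controlled and field buds in this change gave 0 rows in Marquette, with 903 at an unadjusted p under 0.05, and 0 in Brianna, with 1020.

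Brianna against Marquette gave 0 rows in the field and 0 under controlled chilling (edgeR, adjusted p). Rows with an unadjusted p under 0.05 numbered 990 and 896, and the largest differences were 4.03% and 3.56%. Across the 25 comparisons, 4.75% of all tests had an unadjusted p under 0.05. That is somewhat fewer than chance gives, so the edgeR test was slightly conservative as well.

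What the tests could detect was simulated for 2 of the 25 comparisons. Simulated counts had the same library sizes and counting noise alone (Poisson), with no added spread between replicates. In these counts the edgeR test recovered 50 of 50 rows raised by 5% for controlled against field in Marquette. False calls among the other rows numbered 10. For 4 March against 20 November in field Brianna, the edgeR test recovered 4 of 50 rows raised by 5%, 40 of 50 raised by 10% and 50 of 50 raised by 20%, with 6 false calls. There limma voom recovered 2, 35 and 50 of 50, and DESeq2 recovered 0, 22 and 50 of 50, at rises of 5%, 10% and 20%. Rises of 5%, 10%, 20% and 50% were placed together in a single simulated table per comparison, and falls were not tried. The rows with larger rises loosen the adjusted threshold, so small rises may be recovered less often where fewer rows change. These recoveries apply to the rows of the deposited table and not to transcripts of grapevine buds.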

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

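All 25 comparisons called 0 rows, also with DESeq2-type size factors, DESeq2 or the replicate block. The block's 2 Brianna against Marquette values do not check the cultivar means. DESeq2 was conservative, with 174 to 526 rows at an unadjusted p under 0.05. Removing the filter, or asking for at least 5 CPM in at least 3 libraries, took out no row, so these alternatives test nothing. For 4 March against 20 November in controlled Marquette, limma voom with sample weights called 1 row and the fit on only the libraries compared called 1, the row at position 7765 in both (adjusted p 0.0488 and 0.0475, changes of -8.54% and -8.55%, against an adjusted p of 0.0574 in the edgeR fit of all libraries); the cause was not tested. Leaving out each library gave 0 to 2 rows in that comparison: 2 without replicate 2 of controlled Marquette on 20 November (positions 7765 and 15016) and 1 without replicate 3 on 4 March (position 7765). It gave 0 to 1 for controlled against field Brianna in January (1 without controlled replicate 3, position 18691) and 0 to 1 on 12 February (1 without controlled replicate 3, position 18776). These positions were picked after their values were seen, and p was adjusted within each comparison only. Some regroupings of the libraries, described below, also called up to 2 rows in a comparison. The other leave-one-out fits, 344 of 348 values, gave 0. Same-numbered libraries correlated at -0.000186 on average (different numbers, 9.97e-05), and 19 of 60 libraries correlated best with their own number. Whether the numbers pair the samples is undecided, since values close to equal-chance noise correlate near 0 either way. Set tests and their alternatives were not run, since no row was matched to a gene.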

Other observations

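The tests of what could have made this table were all chosen after its values were seen. Every row of a library had about the same count. Measured counts whose rows were only reordered or renamed would keep the wide range of transcript levels, and the largest ratio of highest to lowest row within a library was 1.421, which argues against that. Counts scaled row by row or quantile by quantile were predicted to leave rows that differ in noise. The SD over rows of the variance-to-mean index was 0.1847, within the 0.1809 to 0.1869 of 200 simulated equal-chance tables. No scaled table was simulated, so such scaling is not excluded. Exchanged sample labels would leave libraries that share profiles in other sets, and the largest eigenvalue of the library correlation matrix was 1.102, below the highest simulated value of 1.12. Exchanging labels could not make the rows of a library equal, so this value shows only that no hidden sets of similar libraries were seen. Numbers drawn at random with an equal chance for every row were compared with the table directly. The variance over the mean across rows averaged 1.003 over libraries, inside the simulated extremes of 0.9966 to 1.004, although only 2 of 200 simulations reached it. Of 13 statistics, 11 lay inside the simulated 95% range and 13 within the extremes. The 2 outside were this average and the mean over rows of the variance-to-mean index, also 1.003, which are nearly the same quantity. Others among the 13 overlap too, so they are not separate tests. A candidate explanation is that the deposited values are placeholder or simulated numbers; how the file came about was not tested, and no biological explanation was tested.

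Regrouping the libraries tested nothing, because the real grouping called 0 rows in all 25 comparisons and every split gives at least 0. As many rows as the real grouping were called in 100 of 100 splits in 11 comparisons, and in 10 of 10 in the 14 comparisons of 3 libraries with 3. The highest other split called 2 rows in both sets.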
